A study of Homo sapiens with 12 samples.

How the data were processed

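The data are bulk RNA sequencing of 12 libraries from established human oesophageal squamous cell carcinoma lines. KYSE180 was sampled as a native control and with CDCA7 overexpression, and KYSE150 as a native control and with a short hairpin RNA against CDCA7 (shCDCA7), with 3 libraries in each of the 4 groups. Groups were taken from the sample labels, and each of the 12 columns of values was matched to 1 label. The labels do not say that replicates came from separate cultures, so a p-value here measures the spread between these samples, which may be technical.

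The deposited table holds 1 value per gene and library without naming its unit. The values are FPKM: each value multiplied by the gene length in the same table is a whole multiple of 1 step per library for 100% of the genes above 0 (tolerance 0.01 reads), so the whole reads behind each value were recovered. The deposited FPKM are scaled per kilobase of that length and by an effective library size. That size equals a median-of-ratios size factor computed over all 12 libraries, multiplied by 17642232 reads, the same constant for every library. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 and compared with DESeq2 1.20.0, with mm10 given as the genome build. That build is a mouse build, whereas the identifiers, start and end positions of all 58735 genes in the table match GENCODE 29 for human GRCh38, which was used here for chromosomes and GC content. The counting tool is not given in the sources used here.

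Recovered reads summed to between 16.3 M and 19.6 M per library. A single read is between 0.0511 and 0.0614 CPM, and this limits only counting error, since the libraries carry no molecular identifiers. A gene was tested when it had at least 10 reads per median-sized library in at least 3 libraries and at least 15 reads in all. The choices of groups, tests, thresholds, gene lists, named genes and most alternatives were written down before the data were examined. The plan put a count model first and limma-trend on log2 of the normalised value plus 1 for a table of normalised values. The deposited values are normalised, so limma-trend was used as planned for such a table. No count model was fitted, although the recovered reads would allow one.

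The tests used R 4.3.3 with limma 3.58.1, and the data.table package in version 1.17.8. For each line the 6 libraries were fitted with the group as the only term on log2(FPKM + 1), with an intensity-dependent prior variance. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Because of the added 1, log2 changes of genes near or under 1 FPKM are smaller than the ratio of their FPKM. Differences between the lines, and between the 2 control groups, came from 1 fit of all 12 libraries with 4 groups. The difference written down in advance was (overexpression minus KYSE180 control) minus (KYSE150 control minus shCDCA7). The difference of the 2 manipulations, (overexpression minus KYSE180 control) minus (shCDCA7 minus KYSE150 control), was added after the data were seen. Overlaps of called genes were compared with the product of the list sizes over the genes tested in both lines, without a p since genes are not independent. The comparisons in the 2 lines share no library.

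The 33 gene lists cover signalling, cell cycle, metabolic, stress and epithelial programmes and markers of fibroblasts, leukocytes and endothelial cells. A list with at least 5 tested members was compared with all other tested genes by camera with a preset correlation of 0.01, adjusted over the lists. Camera with a correlation estimated for each list, and the rotation test fry, which asks whether the members move 1 way on balance without comparing them with other genes, were alternatives. Members were counted over all genes tested and again adjusted over the list alone.

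Named genes follow a rule with these parts. The genes in the study's title come first. Then come genes from the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 3, a gene symbol and no overlap between the groups. From each list described, up to 3 called members per direction are named, with some of the classical transition markers whether called or not. For both lines together up to 8 genes per direction are named by the smaller of the 2 changes, and for the controls the 5 largest differences each way under the same conditions of level and overlap. A gene named outside the rule is marked as chosen after its values were seen.

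The alternatives were TMM, upper-quartile, within-line median-of-ratios and total-read scaling, other filters, an added 0.1 in place of 1, limma-voom on the recovered reads, stricter thresholds, a fit of all 12 libraries, a replicate block, and leaving out each library in turn. Removal of each library's GC trend and scaling without mitochondrial genes were added after the data were seen. The fits were also tested on simulated data with the same design and 200 changed genes. In KYSE180-like data 84.7% of tested genes changed 2-fold and 98.0% of those changed 4-fold were recovered, with 8.37% of calls false. The corresponding KYSE150-like values were 84.4%, 98.0% and 7.54%. Both shares of false calls were higher than the adjusted p threshold of 0.05 allows. A list raised 1.5-fold was called in both sets, and 0 other lists were. The simulation gave every library of a group the same spread and so contains no library that stands apart. It gave every gene of a line the same dispersion, 0.0192 for KYSE180 and 0.0189 for KYSE150. The shares recovered and false therefore do not cover genes with a wider spread. It also drew each gene independently of the others, so members of a list were not correlated. The 0 other lists therefore do not test whether the preset correlation is high enough for the real lists. Figures were drawn with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.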

Results

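RNA was measured by sequencing in 12 libraries from 2 human oesophageal squamous cell carcinoma lines. CDCA7, a nuclear protein that works with the chromatin remodeller HELLS, was overexpressed in KYSE180 and lowered with a hairpin RNA in KYSE150, each against native cells of the same line and with 3 libraries per group. Library totals ran from 16.3 M to 19.6 M reads, with group means of 17.2 ± 0.796 M reads (SD, n = 3) in KYSE180 controls, 17.7 ± 0.899 in overexpressing cells, 18.6 ± 0.893 in KYSE150 controls and 17.2 ± 0.911 in shCDCA7 cells. Values are FPKM as deposited, given as mean ± SD with n = 3, and changes are log2 differences of manipulated minus control libraries from limma-trend, with adjusted p.

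The study's question is whether CDCA7 acts on the mesenchymal transition driven by TGF-β through SMAD4, the shared mediator of that pathway, and SMAD7, its inhibitor. CDCA7 (ENSG00000144354, chromosome 2, 173354820 to 173368997 on GRCh38) stood at 24, 18.2 and 17.4 FPKM in the KYSE180 controls and at 44.6, 59.1 and 57.9 FPKM with overexpression. It rose by 1.40 on the log2 scale (SE 0.17, adjusted p = 0.00947). In KYSE150 it stood at 27.4, 25.6 and 25.6 FPKM in the controls and at 9.24, 10.1 and 8.83 FPKM with shCDCA7, and it fell by 1.39 (SE 0.09, adjusted p = 0.00166). The KYSE180 call is lost without overexpression replicate 3 (1.34, adjusted p = 0.0573), and with no filter on low reads (adjusted p = 0.0663). Over its 21 alternatives the adjusted p ran from 0.000218 to 0.0663 and the change from 1.28 to 1.54.

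**Figure D1:**
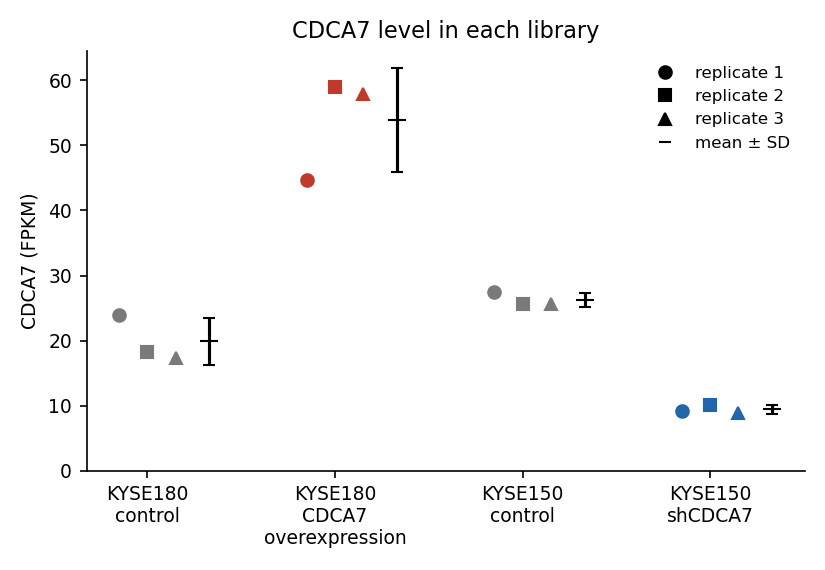
CDCA7 in FPKM for each library, by group, with the mean and SD beside the 3 points of each group. All 3 overexpressing libraries lie above all 3 KYSE180 controls (44.6 FPKM or more against 24 or less), and all 3 shCDCA7 libraries below all 3 KYSE150 controls.

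SMAD4 (chromosome 18, 51028394 to 51085045) was at 4.07 ± 0.274 FPKM in KYSE180 controls and 4.97 ± 0.488 with overexpression, a log2 difference of 0.23 (SE 0.13) that did not pass the test (adjusted p = 0.257). In KYSE150, with less CDCA7, SMAD4 went from 0.625 ± 0.0886 to 0.984 ± 0.0415 FPKM and was called higher (0.29, SE 0.07, adjusted p = 0.0358). Of 20 alternatives, 5 kept that call, the adjusted p ran from 0.0126 to 0.383 and the change from 0.13 to 0.66. At these low levels the added 1 makes the log2 differences of SMAD4 and SMAD7 smaller in size than the ratios of their FPKM. SMAD7 (chromosome 18, 48919853 to 48952052) measured 0.706 ± 0.166 FPKM in KYSE180 controls and 1.27 ± 0.266 with overexpression, a difference of 0.41 (SE 0.12, adjusted p = 0.0764). In KYSE150 it measured 3.22 ± 0.118 and 3.32 ± 1.26 FPKM, a difference of -0.01 (SE 0.23, adjusted p = 0.979). Without shCDCA7 replicate 2 that difference is 0.26 with an adjusted p of 0.0144, the sign is the other one, and over the alternatives the p ran from 0.0144 to 1.

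The comparison in KYSE180 asks which genes change when CDCA7 is raised. The largest rises in log2(FPKM + 1) under the naming rule include TNC, a matrix glycoprotein of motile cells (3.89 ± 5.19 to 20.3 ± 4.13 FPKM), the clock gene PER1 (3.28 ± 0.768 to 25 ± 4.77), the mitochondrial ribosomal RNA MT-RNR2 (2136 ± 510.4 to 11870 ± 1418), the chemokine CXCL14 (2.94 ± 0.426 to 19.8 ± 1.2), the growth factor AREG (11.7 ± 12.2 to 45.0 ± 3.43) and the gelatinase MMP2 (3.34 ± 0.962 to 16.9 ± 0.168). FOSB, an AP-1 subunit, rose by 2.06 on the log2 scale and DBP, a clock output factor, by 2.02. The largest falls include PARP9, HERC6 and other interferon-stimulated genes: IFIT3 went from 99.8 ± 60.3 to 16.8 ± 2.59 FPKM, IFI44 from 75.6 ± 44.2 to 13.5 ± 0.630 and IFIT1 from 66.9 ± 53.3 to 12.6 ± 1.56. The splicing factor SFPQ (64.3 ± 18.1 to 15.6 ± 1.27), the nuclear coregulator NCOA5 (22.9 ± 7.44 to 4.77 ± 0.540) and ZC3H4, which restrains noncoding transcription (11.6 ± 0.994 to 2.50 ± 0.183), also fell. Of 15944 genes tested, 1447 were called, 741 higher and 706 lower, and 280 changed by at least 1 on the log2 scale (189 higher, 91 lower). Groups did not overlap for 5599 genes, where chance gives 10%, and 4777 had an unadjusted p under 0.05. With 5 libraries the count was 87, 2202 and 2335 without control replicates 1, 2 and 3, and 22, 209 and 19 without overexpression replicates 1, 2 and 3. With no filter on low reads it was 3.

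Of 22 genes of the mesenchymal state tested in KYSE180, 9 were higher and 0 lower over all genes, with 13 not passing, and 10 were higher when adjusted over the list alone. The higher ones include TWIST1, a transcription factor that drives the transition (3.58 ± 0.973 to 13.8 ± 2.78 FPKM, log2 1.70, SE 0.20, adjusted p = 0.00947), besides TNC and MMP2. SNAI1, another such factor, rose from 1.19 ± 0.493 to 4.07 ± 1.26 FPKM and the mesenchymal cadherin CDH2 from 0.574 ± 0.539 to 2.77 ± 0.326. SNAI2 (0.17, adjusted p = 0.566) and FN1 (-0.11, adjusted p = 0.704) did not pass, nor did the epithelial cadherin CDH1 (55.1 ± 3.03 to 64.4 ± 7.78 FPKM, 0.22, adjusted p = 0.298). FN1 lay near the floor, and its sign turned without control replicate 2. The list's median change was 0.40 (camera adjusted p = 2.06e-06; adjusted p = 0.245 with an estimated correlation), and without 1 library the higher members ran from 1 to 10. Fibroblast markers, with 5 tested and 1 higher, had the same median of 0.40 (adjusted p = 0.0150; adjusted p = 0.245 with an estimated correlation). Epithelial adhesion genes had a median of 0.13 with 2 of 36 higher, 2 adjusted over the list alone, and the list was not called by camera (adjusted p = 0.127). Fry, which does not compare a list with other genes, called it higher (adjusted p = 0.0142).

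Of 33 TGF-β response genes tested in KYSE180, 7 were higher, 0 lower and 26 did not pass (11 higher adjusted over the list alone; median 0.26, adjusted p = 4.35e-05, and adjusted p = 0.245 with an estimated correlation). Among them JUNB rose from 135 ± 44.8 to 333 ± 48.8 FPKM. Among 34 signalling components 3 were higher, namely BAMBI, TGFB1 and SMURF1, 0 lower and 31 did not pass (4 higher and 1 lower adjusted over the list alone), and that list was not called (median 0.07, adjusted p = 0.127). Immediate-early and AP-1 genes had 17 of 31 higher and 0 lower (22 and 0 adjusted over the list alone), with IER3 going from 167 ± 73.0 to 579 ± 97.4 FPKM and FOS from 30.6 ± 16.1 to 99.4 ± 3.91. Their median was 0.73 (adjusted p = 8.56e-11; adjusted p = 0.245 with an estimated correlation). Without 1 library the higher members ran from 1 to 9 for TGF-β response genes, 1 to 21 for immediate-early and 0 to 10 for basal squamous genes. Scaled to library totals, the median of TGF-β response genes was 0.17. Basal squamous genes had 3 of 20 higher and 0 lower (9 and 0 over the list alone), among them the integrin ITGA6 (30.6 ± 8.89 to 80.9 ± 7.95 FPKM) and NGFR. Their median was 0.55 (adjusted p = 1.16e-05; adjusted p = 0.245 with an estimated correlation).

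Interferon-stimulated genes had 9 of 44 called lower, 0 higher and 35 not passing in KYSE180, and 23 lower when adjusted over the list alone. The median was -1.58 (adjusted p = 3.85e-11; adjusted p = 0.476 with an estimated correlation). The 3 controls differed: the list's mean log2(FPKM + 1) was 5.64, 3.54 and 4.91 in them, against 3.18 to 3.21 with overexpression. Leaving out control replicates 1, 2 and 3 gave 3, 38 and 6 lower members, and leaving out any 1 overexpressing library gave 0, although the median stayed between -1.07 and -2.11. Inflammatory genes had 3 of 24 lower and 0 higher (4 and 0 over the list alone), namely the chemokines CCL2 (4.89 ± 2.62 to 0.603 ± 0.261 FPKM) and CXCL2 and the growth factor CSF1. Their median was -0.38 (adjusted p = 0.0222; adjusted p = 0.594 with an estimated correlation), and the list was not called without control replicate 1 (adjusted p = 0.0655) or 3 (adjusted p = 0.0816), or with library totals (adjusted p = 0.0516). Without 1 library the lower inflammatory members ran from 0 to 11.

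**Figure D2:**
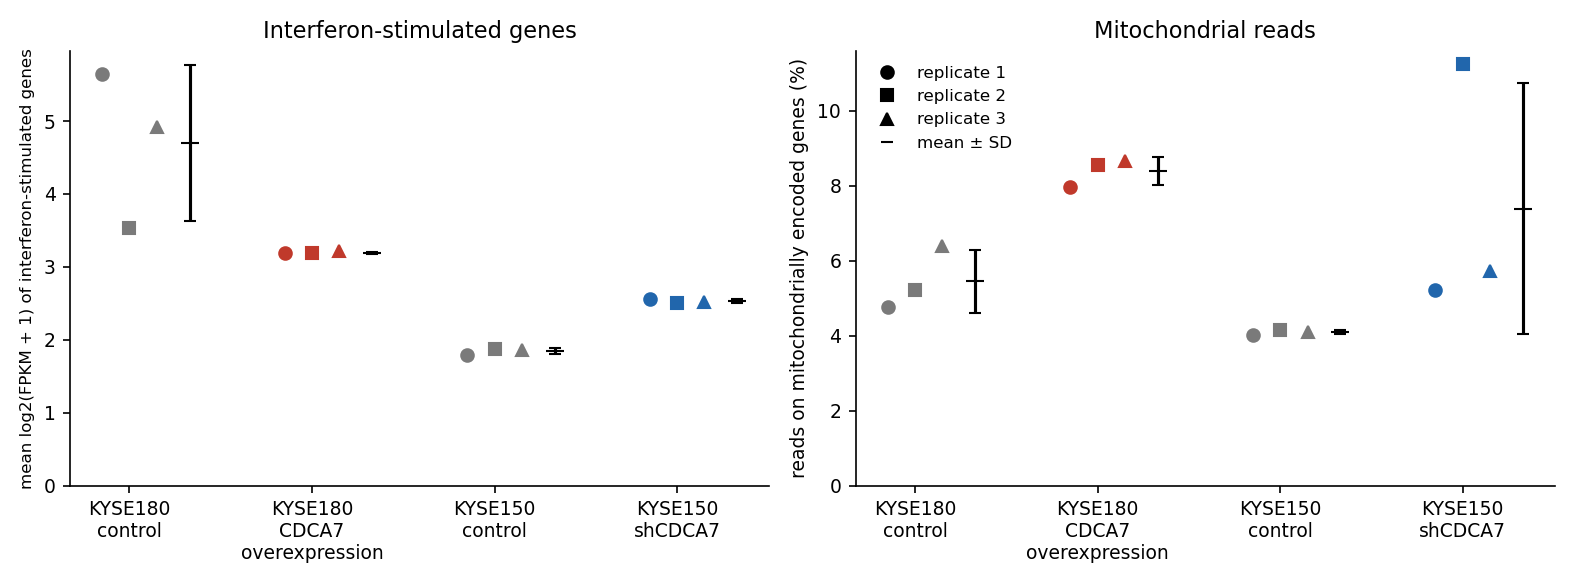
Left, the mean log2(FPKM + 1) of the interferon-stimulated genes in each library; right, the percentage of reads on mitochondrially encoded genes, each with the group mean and SD. KYSE180 controls lie at 5.64, 3.54 and 4.91 for the interferon-stimulated genes, and shCDCA7 replicate 2 has 11.2% mitochondrial reads.

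Growth genes moved in more than 1 direction in KYSE180. Mitosis genes had 9 of 39 higher and 0 lower (20 and 0 over the list alone; median 0.44, adjusted p = 1.23e-08), with PTTG1, the securin, at 49.2 ± 5.75 and 111 ± 23 FPKM and the kinesin KIF2C at 35.9 ± 4.99 and 73.6 ± 6.02. Cytosolic ribosomal protein genes had 3 of 43 higher and 0 lower (15 and 0 over the list alone; median 0.55, adjusted p = 5.47e-11), and replication-dependent histone genes 7 of 25 higher and 0 lower (14 and 0; median 0.56, adjusted p = 2.31e-07). Genes of MYC and ribosome biogenesis had 0 of 35 higher and 5 lower (1 and 9 over the list alone; median -0.43, adjusted p = 5.02e-05), led by the transferrin receptor TFRC (86.8 ± 28.2 to 32.3 ± 3.72 FPKM). G1/S and replication genes had 0 of 44 higher and 1 lower, the cyclin CCNE2 (0 and 5 over the list alone; median -0.32, adjusted p = 4.13e-05). With an estimated correlation the adjusted p were 0.476 for mitosis and for ribosomal proteins, 0.114 for histones, 0.580 for MYC and 0.594 for G1/S. Without 1 library the higher members ran from 0 to 15 for mitosis, 0 to 7 for ribosomal proteins and 0 to 11 for histones. The lower ones ran from 0 to 20 for MYC and 0 to 19 for G1/S. HELLS, the partner of CDCA7, fell from 6.02 ± 0.401 to 3.97 ± 0.355 FPKM (-0.50, SE 0.13, adjusted p = 0.0480). That call lies just under the threshold. In KYSE180 only 3 genes were called with no filter on low reads and 19 without overexpression replicate 3.

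The stress lists of KYSE180 follow. The unfolded protein and amino acid stress list had 7 of 34 higher and 1 lower, the cystine transporter SLC7A11 (13 and 2 over the list alone; median 0.36, adjusted p = 9.62e-06), with the stress factor DDIT3 at 8.61 ± 4.56 and 28.5 ± 5.07 FPKM and the chaperone HSPA5 at 349 ± 164 and 848 ± 81.8. Targets of p53 went both ways, 4 of 25 higher and 3 lower (6 and 3 over the list alone; median 0.27, adjusted p = 0.0222): the cell cycle inhibitor CDKN1A rose (8.32 ± 1.21 to 20.8 ± 0.834 FPKM) and the death receptor FAS fell (7.61 ± 1.67 to 3.38 ± 0.238). Mitochondrially encoded genes had 3 of 15 higher (3 over the list alone; median 0.46, adjusted p = 0.0138), and the 3 were the ribosomal RNAs MT-RNR1 and MT-RNR2 and MT-ND6. Their share of all reads was 5.45% ± 0.837 in controls and 8.39% ± 0.367 with overexpression. Matrix metalloproteinases (2 of 21 higher, 3 over the list alone, median 0.17, adjusted p = 0.0173), collagens and laminins (1 of 24, NID1, 1 over the list alone, median 0.27, adjusted p = 0.00195) and 5 fibroblast genes (1 higher, FBLN2 at 0.394 ± 0.101 FPKM, 2 over the list alone, median 0.40, adjusted p = 0.0150) were called higher too. With an estimated correlation the adjusted p of these 6 lists were 0.476, 0.245, 0.476, 0.476, 0.476 and 0.245 in the order given. The higher members without 1 library ran from 0 to 13 for the stress list, 0 to 6 for p53 targets, 0 to 3 for mitochondrially encoded genes, 0 to 5 for metalloproteinases, 0 to 3 for collagens and 0 to 2 for fibroblast genes. With library totals the medians of p53 targets and collagens were 0.15 and 0.16. Without control replicate 2 the metalloproteinases (adjusted p = 0.126) and collagens (adjusted p = 0.0692) were not called. In all 17 lists were called with the preset correlation and 0 with an estimated one. Leukocyte markers had 3 tested members, too few for a test, and 6 endothelial markers gave a median of -0.06 and a mean of 0.05 without a call (adjusted p = 0.958).

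In KYSE150 the comparison asks which genes change when CDCA7 is lowered. The antiviral genes IFIT1 (5.94 ± 1.02 to 35.0 ± 2.25 FPKM), OASL (5.68 ± 0.908 to 33.3 ± 3.76) and IFIT3 (4.37 ± 0.678 to 25.4 ± 11.3) were among the largest rises, with the histone gene HIST2H2BE (2.42 ± 0.437 to 17.4 ± 6.02), the mitochondrial ribosomal RNA MT-RNR2 and the adhesion gene NECTIN4. The falls were led by HPS6, which serves lysosome-related organelles (15 ± 0.762 to 2.09 ± 0.251 FPKM), TFRC (85.3 ± 4.80 to 20.4 ± 5.44), the arginine methyltransferase PRMT6 (12.1 ± 0.245 to 2.62 ± 0.327), the death adaptor FADD (13 ± 0.210 to 3.17 ± 1.08) and the heat shock gene HSPA1A (33.8 ± 4.99 to 9.79 ± 0.429). Of 14342 genes tested, 2854 were called, 1440 higher and 1414 lower, and 341 changed by at least 1 on the log2 scale (175 higher, 166 lower). Groups did not overlap for 6860 genes (chance gives 10%), and 5268 had an unadjusted p under 0.05. With 5 libraries the count was 569, 545 and 777 without control replicates 1, 2 and 3, and 1792, 7982 and 1544 without shCDCA7 replicates 1, 2 and 3; with no filter it was 1554.

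The library of shCDCA7 replicate 2 stood apart from the others. It had 11.2% mitochondrial reads against 5.2% and 5.73% in replicates 1 and 3 and 4.09% ± 0.0627 in the controls, and 13.1% of its reads fell on its 10 most abundant genes. Across genes its log2(FPKM + 1) correlated at 0.947 and 0.951 with replicates 1 and 3, which correlated at 0.995 with each other. The log2 changes in KYSE150 correlated with GC content across genes at -0.37 with it and -0.12 without it, and at -0.01 in KYSE180; genes are not independent replicates. All 2854 called genes were also called, in the same direction, among the 7982 without it.

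Of 44 replication genes tested in KYSE150, 0 were higher, 19 lower and 25 did not pass, and adjusted over the list alone 1 was higher and 28 lower. The factor E2F1, which drives entry into S phase, went from 26.3 ± 0.545 to 12.2 ± 3.73 FPKM, MCM10 from 16.5 ± 0.190 to 8.61 ± 1.93 and CDC45 from 14.5 ± 1.06 to 8.34 ± 1.81. The median was -0.44 (adjusted p = 2.17e-07; adjusted p = 0.228 with an estimated correlation), and without 1 library the lower members ran from 1 to 37, with the 37 without shCDCA7 replicate 2. In the list of CDCA7, HELLS and DNA methylation genes, 2 of 18 were higher and 3 lower (3 and 4 over the list alone), and the list was not called (median -0.09, adjusted p = 0.425). UHRF1, which brings DNMT1 to replicating DNA, fell from 27.8 ± 0.554 to 13.3 ± 0.711 FPKM and DNMT1, the maintenance methyltransferase, from 30.5 ± 1.11 to 21.4 ± 1.2, while HELLS differed by -0.16 (adjusted p = 0.507). It was called lower without shCDCA7 replicate 2 (-0.32, adjusted p = 0.00673), with GC trends removed (-0.38, adjusted p = 0.0217) and with library totals (-0.39, adjusted p = 0.0487). Of 39 mitosis genes 13 were higher and 0 lower (19 and 0 over the list alone; median 0.43, adjusted p = 1.06e-06), with the kinase CDK1 at 28.9 ± 1.95 and 54.2 ± 3.05 FPKM. Histone genes had 9 of 18 higher and 0 lower (12 and 0; median 0.78, adjusted p = 5.16e-07) and ribosomal proteins 9 of 43 higher and 0 lower (16 and 0; median 0.29, adjusted p = 1.62e-06). With an estimated correlation these last 3 lists had an adjusted p of 0.366, 0.222 and 0.194. When shCDCA7 replicate 2 was left out, 28 mitosis genes were higher and 5 lower, with a median of 0.27. Histone genes then had 17 higher and ribosomal proteins 35, with 0 lower, and the DNA methylation list had 4 higher and 8 lower. The fewest higher without 1 library were 3, 3 and 0 for mitosis, histones and ribosomal proteins. Scaled to library totals, the medians were 0.02 for ribosomal proteins (0.07 without mitochondrial genes in the scaling), 0.22 for mitosis and -0.69 for replication genes. That of the DNA methylation list was -0.33, and the list stayed uncalled.

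Of 38 interferon-stimulated genes tested in KYSE150, 19 were higher, 0 lower and 19 did not pass (23 and 0 adjusted over the list alone; median 0.56, adjusted p = 4.30e-09, and adjusted p = 0.0920 with an estimated correlation). The list's mean log2(FPKM + 1) was 1.80, 1.88 and 1.86 in the controls and 2.56, 2.51 and 2.52 with shCDCA7. Without shCDCA7 replicate 2, 29 were higher and 2 lower, and without control replicate 1, 12 were higher. Inflammatory genes had 10 of 21 higher and 0 lower (13 and 0 over the list alone; median 0.62, adjusted p = 3.08e-05, and adjusted p = 0.222 with an estimated correlation), led by the chemokine CCL5 (0.763 ± 0.375 to 11.4 ± 4.57 FPKM), the NF-κB inhibitor NFKBIA and the cytokine IL1A, and without 1 library 4 to 17 were higher. The inflammatory median was 0.41 with library totals.

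Of 35 epithelial adhesion genes tested in KYSE150, 13 were higher, 2 lower and 20 did not pass (16 and 3 adjusted over the list alone; median 0.45, adjusted p = 3.08e-05, and adjusted p = 0.0920 with an estimated correlation). The higher ones include the claudin CLDN4 (62.7 ± 3.07 to 177 ± 73.9 FPKM), occludin OCLN (3.30 ± 0.341 to 7.86 ± 0.708) and OVOL1, a repressor of the mesenchymal transition (0.502 ± 0.0735 to 2.43 ± 0.366), while the plakophilin PKP3 fell. CDH1 (59.1 ± 1.51 to 93.6 ± 29.1 FPKM, 0.61, adjusted p = 0.0787) did not pass. Mesenchymal genes had 2 of 16 higher, the integrins ITGB1 and ITGA5, 0 lower and 14 not passing (2 and 0 over the list alone). The list was not called by camera (median 0.17, adjusted p = 0.0819), whereas fry called it higher (adjusted p = 0.0238). VIM (0.45, adjusted p = 0.0765), FN1 (0.46, adjusted p = 0.217), TWIST1 (0.17, adjusted p = 0.640) and SNAI2 (0.02, adjusted p = 0.934) did not pass, and the signs of TWIST1 and SNAI2 turn when libraries are scaled to their totals. With shCDCA7 replicate 2 left out, CDH1 (0.37, adjusted p = 0.000365), VIM (0.28, adjusted p = 0.0120) and TWIST1 (0.44, adjusted p = 0.000790) were called higher. CDH1 and VIM were also called with GC trends removed (adjusted p = 0.0475 and 0.0456) and in the fit of all 12 libraries (0.0332 and 0.0182), and VIM without shCDCA7 replicate 1 (0.0483). TGF-β response genes had 5 of 32 higher and 1 lower (7 and 1 over the list alone; median 0.23, adjusted p = 0.00874, and adjusted p = 0.228 with an estimated correlation). The matricellular genes CYR61 (505 ± 34.8 to 1665 ± 295 FPKM) and CTGF rose and LTBP2 fell. Signalling components had 7 of 33 higher, among them the ligand TGFB2, and 4 lower (8 and 5 over the list alone; median 0.02, adjusted p = 0.571). Leaving out shCDCA7 replicate 2, the higher and lower members were 24 and 3 for epithelial adhesion, 7 and 1 for mesenchymal, 15 and 2 for TGF-β response and 12 and 7 for signalling genes. The fewest higher without 1 library were 5, 0, 2 and 0. With library totals the medians of these lists were 0.20, 0.03, 0.06 and -0.14.

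Metabolic lists were called higher in KYSE150. Cholesterol synthesis genes had 11 of 22 higher and 1 lower, PMVK (13 and 1 over the list alone; median 0.39, adjusted p = 3.08e-05), with the sterol oxidase MSMO1 at 36.0 ± 4.33 and 96.4 ± 1.75 FPKM and the sterol carrier STARD4 at 7.59 ± 0.347 and 18.4 ± 1.01. Targets of NRF2, the oxidative stress factor, had 13 of 28 higher and 1 lower (14 and 1; median 0.40, adjusted p = 7.88e-06), with thioredoxin reductase TXNRD1 at 50.1 ± 1.78 and 98.0 ± 4.07 FPKM. Basal squamous genes had 8 of 18 higher, among them KRT17, and 1 lower (10 and 1; median 0.40, adjusted p = 0.00794). Immediate-early genes had 7 of 29 higher and 0 lower (7 and 0; median 0.29, adjusted p = 0.00987), led by ATF3 at 23.8 ± 0.0400 and 75.9 ± 9.06 FPKM. The stress list had 8 of 34 higher and 1 lower (9 and 1; median 0.17, adjusted p = 0.0105), oxidative phosphorylation 5 of 35 higher and 0 lower (5 and 0; median 0.18, adjusted p = 0.00987), and mitochondrially encoded genes 2 of 15 higher and 0 lower (2 and 0; median 0.38, adjusted p = 0.0379). With an estimated correlation the adjusted p of these 7 lists were 0.0920, 0.209, 0.222, 0.583, 0.463, 0.292 and 0.668 in the order given. Scaled to library totals, the medians of the stress list (-0.04) and of oxidative phosphorylation (-0.07) turn negative, as does the latter without mitochondrial genes in the scaling (-0.02). Those of cholesterol (0.15), NRF2 (0.17), basal squamous (0.15), immediate-early (0.13) and mitochondrially encoded genes (0.12) become smaller with totals. Oxidative phosphorylation was not called with totals (adjusted p = 0.109), nor were mitochondrially encoded genes with GC trends removed (adjusted p = 0.0731). Calls ended without shCDCA7 replicate 1 for immediate-early (adjusted p = 0.0564), stress (0.0755) and oxidative phosphorylation genes (0.108), without replicate 3 for immediate-early genes (0.0565), and without replicate 2 (0.366) or control replicate 1 (0.0582) for mitochondrially encoded genes. The higher and lower members of the 7 lists without shCDCA7 replicate 2 were 17 and 1, 21 and 1, 12 and 5, 20 and 7, 18 and 3, 26 and 2, and 7 and 3 in the same order. The median of mitochondrially encoded genes was then 0.13. The fewest higher without 1 library were 7, 4, 1, 4, 4, 0 and 0. In all 15 lists were called with the preset correlation and 0 with an estimated one. Leukocyte and endothelial markers had 3 and 4 tested members, too few for a test.

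**Figure D3:**
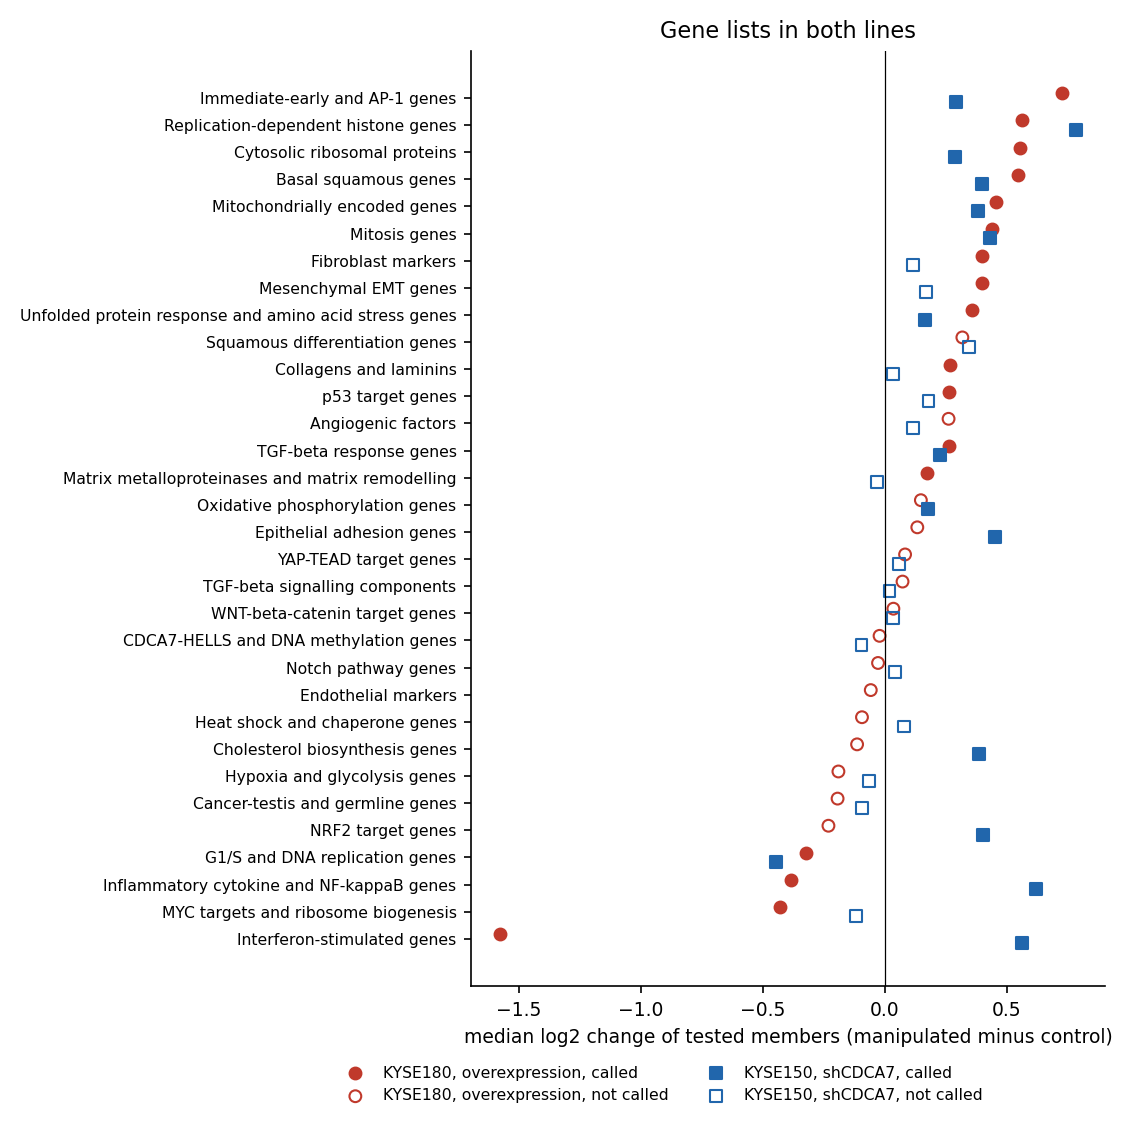
Median log2 change of the tested members of each gene list, manipulated minus control, in KYSE180 (circles) and KYSE150 (squares); filled marks passed camera with the preset correlation. Interferon-stimulated genes lie at -1.58 in KYSE180 and 0.56 in KYSE150; scaled to library totals, the KYSE150 medians of the stress list (-0.04) and of oxidative phosphorylation (-0.07) are negative.

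Since CDCA7 is raised in 1 line and lowered in the other, genes that follow it would move in opposite directions. Besides CDCA7 itself, the genes higher with overexpression and lower with shCDCA7 included TNS4, a tensin of focal adhesions (log2 0.96 and -1.03), the connexin GJB5 (0.95 and -1.12), the hormone-like PTHLH (1.70 and -0.80) and the transcription factors ZBED2 (0.95 and -1.77) and TEF (1.01 and -0.63). The genes that moved the other way were led by IFIT3 (-2.34 and 2.23), IFI44 (-2.19 and 2.54), IFIT1 (-2.00 and 2.39) and the RNA sensors IFIH1 (-1.19 and 1.27) and DDX58 (-1.69 and 1.11). More genes moved the same way in both lines: PER1 (2.60 and 1.70), the clock repressor NR1D1 (1.52 and 1.24), GADD45B, PIM1 and HERPUD1 rose in both, and ZC3H4 (-1.85 and -1.44), NCOA5 (-2.00 and -1.38), TFRC (-1.35 and -2.04) and PPP1R10 (-1.26 and -1.58) fell in both. Among 13377 genes tested in both lines, 433 were called in both, 23 in opposite directions (14 and 9) and 410 in the same direction (215 up, 195 down), which is 94.7%. Independent lists would share 114 in opposite and 114 in the same directions. Across genes the changes correlated at 0.394 (Pearson) and 0.429 (Spearman), with no p since genes are not independent. Without shCDCA7 replicate 2 the counts were 71 and 754 against 323 and 325 for independent lists. Without control replicates 1, 2 and 3 of KYSE180 they were 4 and 21, 74 and 482, and 36 and 591, without overexpression replicates 1, 2 and 3 they were 1 and 9, 3 and 59, and 0 and 5, and without control replicates 1, 2 and 3 of KYSE150 they were 11 and 136, 11 and 128, and 13 and 175.

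**Figure D4:**
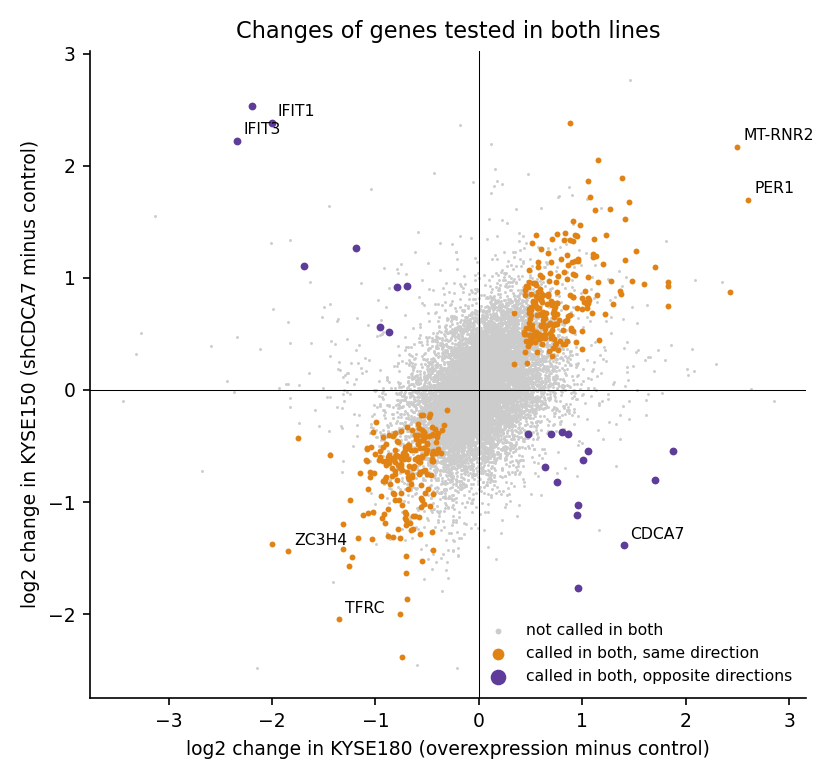
Log2 changes of the 13377 genes tested in both lines, overexpression minus control in KYSE180 (x axis) and shCDCA7 minus control in KYSE150 (y axis). Of the genes called in both, 410 moved in the same direction and 23, CDCA7 and IFIT1 among them, in opposite directions.

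A difference between the lines was tested directly in the fit of all 12 libraries. That fit pools the spread of each gene over groups that differed in spread. Replicates correlated at 0.964 to 0.982 in KYSE180 controls and at 0.996 in KYSE150 controls. Pooled in this way, 2893 genes were called in KYSE180 against 1447 in its own fit. The counts given here and between the controls rest on that pooled spread. Written as higher against lower CDCA7, the effect differed between KYSE180 and KYSE150 for 4850 of 17088 genes, 2398 higher and 2452 lower in KYSE180. On this scale a gene that moved the same way after both manipulations differs. Histone genes (median difference 1.06, 17 of 26 higher), epithelial adhesion genes (0.55, 15 of 36 higher and 2 lower) and mesenchymal genes (0.45, 11 of 26 higher) each passed camera with an estimated correlation (adjusted p = 0.0188 for each). Each of these lists had a median above 0 after both manipulations, for histone genes 0.56 in KYSE180 and 0.78 in KYSE150. Manipulated against control, histone genes did not differ (median -0.12, camera adjusted p = 0.903). The limits of handling and batch given below for changes shared by both lines apply to these lists. Written as manipulated against control, 952 genes differed, 491 higher and 461 lower with overexpression, and 3797 had an unadjusted p under 0.05. Interferon-stimulated genes differed by a median of -2.09 with 15 of 44 members lower (adjusted p = 4.64e-21; adjusted p = 0.348 with an estimated correlation) and inflammatory genes by -0.81 with 7 of 27 lower (adjusted p = 2.54e-07; adjusted p = 0.348). Mesenchymal genes differed by 0.20 with 7 of 26 higher (adjusted p = 0.00260; adjusted p = 0.101), and epithelial adhesion genes by -0.28 with 4 of 36 lower (adjusted p = 0.00627; adjusted p = 0.101), where the second p of each has an estimated correlation. Line, direction of the manipulation and any batch between lines coincide in this design.

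The controls show how the lines differ before any manipulation. KYSE180 had the simple-epithelial keratin KRT19 at 574 ± 44.8 FPKM against 0.0425 ± 0.0224 in KYSE150, KRT13 at 384 ± 137 against 0.113 ± 0.0233 and the lineage factor SOX2 at 211 ± 82.8 against 0.121 ± 0.0944. KYSE150 had the metallothionein MT1E at 400.03 ± 9.59 FPKM against 0.267 ± 0.249 and the crosslinking enzyme TGM2 at 76.5 ± 4.12 against 0.0271 ± 0.0121. SMAD4 was higher in KYSE180 (4.07 against 0.625 FPKM, log2 1.64, SE 0.10, adjusted p = 1.16e-07), SMAD7 lower (0.706 against 3.22, -1.31, SE 0.20, adjusted p = 0.000155) and CDCA7 lower (19.9 against 26.2, -0.40, SE 0.14, adjusted p = 0.0293). These log2 values are of FPKM + 1, so those of SMAD4 and SMAD7 are smaller in size than the ratios of their FPKM. Interferon-stimulated genes were higher in KYSE180, 40 of 44 with 1 lower (median difference 2.65, adjusted p = 6.37e-08, and adjusted p = 0.824 with an estimated correlation), as were NRF2 targets, 22 of 31 with 2 lower (1.38, adjusted p = 4.35e-07, and adjusted p = 0.580). YAP-TEAD targets were lower, 13 of 22 with 4 higher (-0.93, adjusted p = 0.00189, and adjusted p = 0.260). In all 9905 of 17088 genes differed, 5705 higher and 4200 lower in KYSE180, 3374 of them by at least 1 on the log2 scale.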

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

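Some tests were chosen only after the results they address were seen. They include the tests of shCDCA7 replicate 2 for its depth and for a swap. They also include those of the changes shared by both lines for GC trends, replicate 2 and handling. The interferon-stimulated genes were tested without single libraries, against the other lists in relabellings and for a response to the construct, all likewise chosen afterwards. So was the difference between the 2 manipulations. The GC test of shCDCA7 replicate 2 was set before its outcome was seen. So were the counts of genes and lists over other splits and the counts of genes over relabellings.

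The effect of higher against lower CDCA7 differed between the lines for 4850 genes in the test of that difference. A gene that moved the same way after both manipulations differs on this scale. The count therefore takes in the first pattern below and shares its limits, among them handling, batch and carrying a construct. Among 100 relabellings of the libraries within the lines, drawn from 200, the real one alone gave as many, 1 of 100. The highest of the others gave 800. A real change in 1 line is enough to raise this count, so the relabellings argue only against no change in either line. They do not test whether the change differs between the lines. Manipulated against control, the change differed between overexpression and shCDCA7 for 952 genes. Here 2 of the 100 relabellings, the real one included, gave as many, and the other gave 1073. That relabelling, and the one with 800 genes, kept the real groups of KYSE150 and regrouped KYSE180, so the KYSE150 groups alone can give such counts. Interferon-stimulated genes differed by a median log2 of -2.09 and inflammatory genes by -0.81 between the manipulations with a preset correlation (adjusted p = 4.64e-21 and 2.54e-07), but neither list passed with an estimated one (adjusted p = 0.348 for both).

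Within a line, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split gave 1447 called genes in KYSE180, 2854 in KYSE150 and 9905 between the controls, 1 of 10 splits each, and the highest other split gave 0 in each. For the gene lists with a preset correlation the real splits gave 17 and 15 lists, 2 of 10 splits gave as many in each line, and the highest other split gave 17 in each line. The lowest other split gave 6 lists in KYSE180 and 3 in KYSE150, although no other split called a gene. The number of lists called with the preset correlation therefore does not set the real groups apart.

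The first pattern is that 410 genes moved the same way in both lines although CDCA7 was raised in one and lowered in the other. The highest other of 100 relabellings gave 0, which only repeats the counts within the lines, and the correlation of 0.394 across genes does not mark the pattern, as a relabelling reached 0.449 in size. With each library's GC trend removed 549 genes moved the same way (177 for independent lists), and without shCDCA7 replicate 2 754 did (325), which argues against either as the whole cause. Handling or batch shared by the manipulated libraries may account for part of it and cannot be told apart from the manipulation, because no label gives a control and a manipulated library that shared handling: mitochondrial ribosomal RNA took 1.77% to 2.15% of reads with overexpression against 0.319% to 0.506% in its controls, and 1.74% to 3.82% with shCDCA7 against 0.677% to 0.739%, at least 2.35 times the highest control in each line. A response of both lines to carrying a construct, with native cells as the only controls, or to any departure of CDCA7 from its usual level also stays open and was not tested.

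The second pattern is shCDCA7 replicate 2. Its 17.03 M reads lie within the 16.4 M to 19.6 M of the other KYSE150 libraries, which argues against depth. Its CDCA7 level of 10.1 FPKM is far under every KYSE150 control, and no control has a low level, which argues against a swap with a control. Removing GC trends raised its mean correlation with replicates 1 and 3 from 0.953 to 0.967, where those correlate at 0.995 and the controls at 0.996 or more, so that it closed 33.3% of the gap and GC bias is not the whole cause. The state of its cells or RNA, which 11.2% mitochondrial reads may reflect, stays open, and no biological explanation was tested, since no label sets it apart.

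The third pattern is the interferon-stimulated genes, lower with overexpression and higher with shCDCA7, whose medians differ by 2.14. The real grouping alone, 1 of 100 relabellings, gave as large a gap in any list, and the highest other gave 1.94. A real shift in 1 line is enough for this share. It therefore speaks against no shift in either line and leaves chance open for each line alone. The 10 splits of each line are too few for a share under 0.05. Relabellings that kept the KYSE180 groups gave 1.34 to 1.94, so most of the gap is the KYSE180 median. A relabelling that regrouped KYSE180 and kept the KYSE150 groups gave 1.86. In each of the 12 fits without 1 library the list's median kept its sign and a size of at least 0.542, which argues against 1 library as the source of the direction, although without control replicate 2 of KYSE180 the members called lower went from 9 to 38, and without any 1 overexpressing library to 0. A response to the construct or its delivery is a candidate explanation for the rise in KYSE150: IFNL1, an interferon that foreign nucleic acid induces, was at 0.597 FPKM or more in all 3 shCDCA7 libraries and at 0.0600 or less in the controls, whereas IFNB1, another such interferon, had 0 reads in all 6 KYSE150 libraries. It cannot be told apart from an effect of CDCA7, because no control with the same construct is labelled. In KYSE180 the controls differ among themselves (5.64, 3.54 and 4.91) and the list did not pass with an estimated correlation (adjusted p = 0.476), and an effect of CDCA7 on these genes stays open in both lines.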

How the results depend on the processing

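The limma-voom overlap, the GC and mitochondrial settings and the overlaps without a filter or with library totals were chosen after the results were seen. The count-model tests in the plan were not run, although recovered reads, used for voom and TMM, would allow them. Genes called both as reported and under another setting had the same direction in each of the settings run for each line. For the 89 called genes chosen by the naming rule in KYSE180, 1256 of 1865 values kept direction and call and 609 lost the call, and for the 119 in KYSE150, 1967 of 2489 kept them and 522 lost the call, with 0 reversed. CDCA7 kept its direction in all settings and its call in KYSE150; in KYSE180 the call was lost without a filter (1.40, adjusted p = 0.0663, where more genes were tested) and in 1 of the fits without a library (range 1.31 to 1.54).

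Without a filter on low reads 3 genes were called in KYSE180 and 1554 in KYSE150, 0 in both lines in opposite and 1 in the same direction; 31719 and 28999 genes were then tested. At a log2 size of at least 1 the counts were 280 and 341, 6 opposite and 32 the same, 1635 for the difference between the lines and 3374 between the controls, and at an adjusted p under 0.01 they were 62 and 785. Fitting all 12 libraries gave 2893 in KYSE180, with 17088 genes tested and the spread pooled over both lines, and the cause was not tested. Voom gave 42 genes in opposite directions and library totals 650 in the same direction, and the cause was not tested. Without 1 library, with fewer samples, counts ran from 19 to 2335 in KYSE180, 545 to 7982 in KYSE150, 0 to 74 for opposite and 5 to 754 for the same direction. Lists called with an estimated correlation were 0 in both lines, and fry called 9 in KYSE180 and 22 in KYSE150. Of the lists called as reported, 8 of 17 in KYSE180 and 14 of 15 in KYSE150 passed fry. Those that did not in KYSE180 include interferon-stimulated genes (fry adjusted p = 0.102), mitosis (0.0980), ribosomal proteins (0.102), MYC (0.256) and G1/S genes (0.264). In KYSE150 fry also called lists that camera did not, among them the DNA methylation list (lower, adjusted p = 0.0127).

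With the replicate number as a replicate block, 603 genes were called in KYSE180 and 1001 in KYSE150, with 12 in opposite and 101 in the same direction. Deviations of same-numbered libraries correlated between -0.08 and 0.07, which gives no sign of pairing. With 3 libraries per group this cannot exclude that same-numbered libraries were handled together, and the labels do not say.

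Scaling to library totals moved the median of all genes by -0.08 in KYSE180 and -0.16 in KYSE150, and scaling without mitochondrial genes by -0.13 in KYSE150. The share of called genes that were higher went from 51.2% and 50.5% to 29.1% and 20.5% with totals, and to 35.8% and 24.5% without mitochondrial genes.

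All reversed values belong to genes near 0 and not called as reported. SNAI2 in KYSE150 was at -0.0421 with TMM, -0.00698 with within-line median-of-ratios, -0.22 with totals, -0.14 with GC trends removed, -0.17 without mitochondrial genes in the scaling, and from -0.0533 to 0.0547 without 1 library. TWIST1 was at -0.0675 with totals and -0.0229 without mitochondrial genes. SMAD7 in KYSE150 was at 0.0347 with upper-quartile scaling, 0.14 with GC trends removed, and from -0.16 to 0.26 without 1 library, where the 0.26, without shCDCA7 replicate 2, passed (adjusted p = 0.0144). FN1 in KYSE180 ran from -0.22 to 0.11 without 1 library. The cause was not tested. Depth limits genes under the filter, which were not tested.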

Other observations

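The genes and tests in these paragraphs were picked after their values were seen, except the list results, which were planned. No list of circadian clock genes was fixed or tested, and the clock genes named here did not move in 1 direction. In KYSE180 with overexpression, besides PER1, NR1D1, DBP and TEF, the repressors CRY1 (3.21 ± 0.480 to 5.6 ± 0.101 FPKM, log2 0.66, adjusted p = 0.0314) and CRY2 (3.27 ± 0.776 to 6.06 ± 0.0767, 0.74, adjusted p = 0.0349) and NR1D2 (0.60, adjusted p = 0.0367) rose. BHLHE40, which represses clock output, rose in both lines (0.85 in KYSE180 and 0.99 in KYSE150). In KYSE150 with shCDCA7 the repressor NFIL3 rose from 13 ± 0.912 to 31.8 ± 0.685 FPKM (1.23, adjusted p = 0.00181), ARNTL rose (0.38, adjusted p = 0.0334) and PER2 fell from 2.19 ± 0.182 to 1.14 ± 0.0756 (-0.58, adjusted p = 0.00947), while CLOCK differed by 0.20 (adjusted p = 0.615) there and by -0.10 (adjusted p = 0.680) in KYSE180. Harvest times are not given in the labels.

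Lambda interferon transcripts were few. In KYSE150, IFNL2 was listed at 0 in all 3 controls and at 1.63, 1.59 and 1.24 FPKM with shCDCA7 (19, 16 and 16 reads). In KYSE180, IFNL1 stood at 1.36, 17.5 and 1.42 FPKM in the controls and at 4.91, 3.0 and 4.69 with overexpression. IFNB1 had 10, 33 and 5 reads in the KYSE180 controls and 6, 0 and 1 with overexpression. The control with 17.5 FPKM of IFNL1, replicate 2, had the lowest mean of interferon-stimulated genes among the controls.

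Other lists were not called as reported. Some of them passed when libraries were scaled to their totals: in KYSE180 angiogenic factors (adjusted p = 0.0253), squamous differentiation and NRF2 targets (0.0479 each) and hypoxia and glycolysis genes, the last at 0.0449 without mitochondrial genes in the scaling, and in KYSE150 MYC and ribosome biogenesis genes (0.0454) and p53 targets (0.0497). Scaling to totals also turned the KYSE150 medians of heat shock (-0.18), WNT (-0.18), collagens (-0.17), YAP-TEAD (-0.15), signalling components (-0.14), Notch (-0.13) and angiogenic factors (-0.05), and the KYSE180 medians of YAP-TEAD (-0.03), WNT (-0.03) and signalling components (-0.0125). Cancer-testis genes, many of which DNA methylation silences in other tissues, had 0 of 12 higher and 1 lower in KYSE180 (median -0.19, adjusted p = 0.127) and 0 of 7 changed in KYSE150 (median -0.09, mean 0.01, adjusted p = 0.940; 0 were also called adjusted over the list alone). Squamous differentiation genes had 3 of 21 higher in KYSE180, among them SPRR1A (0.471 ± 0.638 to 5.14 ± 1.60 FPKM) and KRT1, and 1 lower (4 and 3 over the list alone; median 0.32, adjusted p = 0.127), and 2 of 14 higher and 1 lower in KYSE150 (5 and 1; median 0.35, adjusted p = 0.0879). Hypoxia and glycolysis genes had 0 of 32 higher and 2 lower in KYSE180 (1 and 8; median -0.19, adjusted p = 0.0682) and 5 of 31 higher and 3 lower in KYSE150 (5 and 3; median -0.06, mean 0.01, adjusted p = 0.986), where ADM rose (23.3 ± 0.644 to 65.2 ± 18.3 FPKM) and CA9 fell (10.9 ± 0.983 to 3.84 ± 0.532). Angiogenic factors had 2 of 21 higher in KYSE180 (7 over the list alone; median 0.26, adjusted p = 0.0763) and 4 of 18 in KYSE150 (4; median 0.12, adjusted p = 0.0986). NRF2 targets in KYSE180 had 0 of 31 higher and 4 lower (0 and 4; median -0.23, adjusted p = 0.0916).

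Without shCDCA7 replicate 2 some KYSE150 medians of uncalled lists turned: YAP-TEAD to -0.07 with 8 higher and 8 lower, heat shock to -0.06 with 4 and 8, metalloproteinases to 0.05 with 8 and 6, and cancer-testis genes to 0.0035 with 2 and 0. Others changed in their counts of higher and lower members: squamous differentiation to 8 and 1 (median 0.59), hypoxia and glycolysis to 7 and 13, MYC and ribosome biogenesis to 6 and 18, p53 targets to 14 and 3, collagens and laminins to 9 and 5, fibroblast markers to 3 and 0, angiogenic factors to 7 and 1, WNT targets to 4 and 5 and Notch genes to 7 and 4. In KYSE180 without 1 library the lower members ran from 0 to 10 for hypoxia and glycolysis, 0 to 7 for heat shock and 0 to 5 for NRF2 targets and for DNA methylation genes, and the higher ones from 0 to 6 for angiogenic factors and 0 to 5 for squamous differentiation. In the YAP-TEAD list, 3 of 19 were higher and 2 lower in KYSE180 (4 and 4 over the list alone; median 0.08, mean -0.02, adjusted p = 0.646) and 7 of 20 higher and 3 lower in KYSE150 (8 and 4; median 0.06, adjusted p = 0.334). WNT targets had 0 of 15 changed in KYSE180 (2 and 1; adjusted p = 0.854) and 2 of 11 higher, MYC among them (10.7 ± 0.782 to 26.5 ± 6.34 FPKM), and 5 lower in KYSE150 (2 and 5; median 0.03, mean -0.03, adjusted p = 0.535). Notch genes had 2 of 15 higher and 1 lower in KYSE180 (median -0.03, mean 0.03, adjusted p = 0.958) and 2 of 14 higher and 1 lower in KYSE150 (adjusted p = 0.571), and HES1 rose in both lines (35.4 ± 10.8 to 73.4 ± 14.6 FPKM and 10.8 ± 1.78 to 43.9 ± 16.5). Heat shock genes had 1 of 22 higher and 0 lower in KYSE180 (adjusted p = 0.985), and 1 of 22 higher and 3 lower in KYSE150, HSPA1A, HSPA1B and DNAJA1 (median 0.08, mean -0.12, adjusted p = 0.686). In KYSE180 oxidative phosphorylation had 0 of 35 changed (median 0.15, adjusted p = 0.163; 0 over the list alone). In KYSE150, MYC and ribosome biogenesis genes had 2 of 35 higher and 10 lower (median -0.12, adjusted p = 0.0938), p53 targets 5 of 25 higher and 1 lower (0.18, adjusted p = 0.0971), metalloproteinases 4 of 20 higher and 3 lower (median -0.03, mean 0.10, adjusted p = 0.986), with the urokinase PLAU at 17.9 ± 1.16 and 63.0 ± 16.1 FPKM, collagens and laminins 2 of 23 higher (0.03, adjusted p = 0.938) and 5 fibroblast markers 0 higher (0.11, adjusted p = 0.390). In KYSE180, CDCA7, HELLS and DNA methylation genes had 1 of 19 higher and 2 lower (median -0.02, adjusted p = 0.335).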
